A study of Mus musculus with 16 samples.

How the data were processed

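RNA-seq gene tables were taken for 16 libraries of CT26, a mouse colon carcinoma cell line that the labels describe as mouse colorectal cancer cells. The libraries fell into 4 groups by their labels: 3 labelled ARID1A wild type and untreated, 3 labelled ARID1A knockout and untreated, 5 labelled ARID1A knockout with IgG therapy, and 5 labelled ARID1A knockout with PD1 therapy. Each column of the tables was tied to its library by the labels, with 0 columns left over. Per the labels, total RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit, which does not mark the strand of a transcript, and how strand was handled in counting was not given. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the genome builds GRCm38 and mm10.

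The untreated and the treated libraries were deposited in separately made tables. Both count tables were deposited as raw read counts per gene, which were whole numbers with totals that differed between libraries. The FPKM tables were deposited beside them by the authors. In the untreated table, FPKM was the count per kb of a fixed gene length, scaled to the total count of the library. Over 9911 genes with at least 100 counts in every library, the length implied this way differed between libraries by at most 0.0864%. In the treated table, the deposited FPKM held a further scaling factor per library of 0.9496 to 1.078. The untreated table listed 23529 genes, of which 17217 were protein coding and 6307 lncRNA, and 891 had no count in any library. The treated table listed 54532 genes, of which 22046 were protein coding, and 24216 had no count. GENCODE M21, an annotation on GRCm38, held 54495 of the treated gene IDs, and 53585 of them had its start and end. It held 22472 of the untreated gene IDs, but only 449 had its start and end, so the positions given in the untreated table were not on GRCm38 and their build was not settled. Positions from the tables were therefore never compared, and levels were compared across the tables only where the text says so.

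Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package in version 1.17.8. In each comparison, genes were kept by edgeR's filterByExpr, libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit with robust set, glmQLFTest) with an intercept and the group was fitted. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. The number of called genes with an absolute log2 fold change of at least 1 was counted beside it. CPM values used the TMM library sizes, except those of Ptprc and of the marker genes compared across the tables, which were scaled to the total count. The SE of a log2 fold change was derived as its absolute value over the square root of the quasi-likelihood F statistic. SD is the spread between libraries of a group.

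A set of 34 gene lists was fixed before the data were examined: arachidonic acid metabolism, prostaglandin and leukotriene receptors, SWI/SNF complex subunits, interferon response, MHC class I antigen presentation, cytokines and chemokines, angiogenesis factors, epithelial-mesenchymal transition, cell cycle G2/M, DNA replication, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis and desaturation, glutathione and NRF2 targets, TNF/NF-kB targets, mismatch repair and DNA damage response and unfolded protein and amino acid stress response. The others were immediate early and heat shock genes, mitochondrially encoded genes, cytosolic ribosomal proteins, immune checkpoints and exhaustion, and markers of T cells, NK cells, B cells, macrophages, neutrophils, dendritic cells with MHC class II, endothelium, fibroblasts and matrix, keratinocytes, skeletal muscle, adipocytes and erythroid cells. They held 817 genes, of which 750 were in the untreated and 816 in the treated table. Called members were counted over all genes and again adjusted over the list alone. Each list with at least 3 measured members was tested with limma's camera on log2 CPM with a prior count of 3, with the correlation between genes preset at 0.01 and adjusted by Benjamini-Hochberg over the lists. Camera compares a list with all other genes. It was repeated with the correlation estimated from the data, and fry, which asks whether a list's genes move on balance in a single direction and compares it with no other genes, was run beside it.

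The comparisons, their tests, the lists, the settings tried in their place and the rule for named genes were chosen before the data were examined. The rule took Arid1a, and the 5 genes with the largest positive and the 5 with the largest negative log2 fold change among called genes with a mean CPM of at least 5, no overlap between the groups and a symbol that is not a clone model. It also took up to 3 called members with the smallest p from each list of the first tier (the member with the smallest p where none was called), and the called member with the smallest p from each list of the second tier. The alternative settings chosen then were DESeq2's size factors (RLE), upper-quartile factors, DESeq2, limma-voom with sample quality weights, no low-count filter, a filter at a CPM of 1, the replicate number as a block, limma-trend on log2 of the deposited FPKM plus 1 or plus 0.1 with a minimum mean FPKM of 1, the same without a minimum, and leaving out each replicate in turn. Alternatives added after seeing the data were leaving out the mitochondrially encoded genes, removing GC content and gene length trends per library, and leaving out IgG replicates 2 and 5 and PD1 replicate 5 together. No library was left out of the reported values.

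The tests were tried on simulated counts with planted changes and the group sizes of the study. With 3 libraries per group and 13832 genes, edgeR recovered 14 of 67 genes planted at 1.5-fold, 48 of 67 at 2-fold and 59 of 66 at 4-fold, with 7 false calls among 128. With 5 per group and 15899 genes it recovered 14 of 67, 36 of 67 and 57 of 66, with 6 false calls among 113, while DESeq2 made 30 false calls among 171 and 36 among 168. A planted list was called by all 3 list tests in both designs, and 0 random lists were called. Each gene was simulated independently of the others, so this cannot show how often lists of correlated genes are called falsely. Simulated libraries do not carry the differences between real libraries that were found here.

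Total counts per library ran from 28602612 to 38967101 in the untreated table and from 22061724 to 25560937 in the treated table. The median SE of a log2 fold change was 0.154 between the untreated groups and 0.166 between the treated groups. Where a gene had 0 counts in a whole group, its fold is a lower bound against a floor of 3 counts over the group, which covers counting error only. The labels do not say that replicates came from separate cultures or animals, so the p values measure only the spread between these libraries.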

Results

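RNA-seq measured gene expression in CT26 libraries labelled by ARID1A genotype and by therapy. The untreated libraries were 3 labelled wild type and 3 labelled knockout. The treated libraries, all labelled knockout, were 5 given IgG, the control antibody, and 5 given PD1 therapy, which the labels name without its agent (PD1 is a checkpoint receptor of T cells). Total counts were 35915192 to 38967101 per library labelled wild type, 28602612 to 32127662 per untreated library labelled knockout, 22061724 to 25220833 with IgG and 23083469 to 25560937 with PD1. An untreated library detected 18319 to 19003 genes and a treated library 22151 to 24134 genes, from tables made with different annotations. The mitochondrial share of the counts was 1.77% ± 0.0886 (SD, n = 3) in the libraries labelled wild type and 5.61% ± 3.69 (SD, n = 3) in those labelled knockout, where it was 2.57%, 9.72% and 4.53% in replicates 1, 2 and 3. It was 1.21 to 2.71% with IgG and 1.10 to 3.24% with PD1.

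Arid1a (ENSMUSG00000007880), which encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, was more abundant in the untreated libraries labelled knockout than in those labelled wild type. Its level was 128, 131 and 140 CPM in the libraries labelled wild type (133 ± 6.40, SD, n = 3) and 164, 255 and 223 CPM in those labelled knockout (214 ± 46.1, SD, n = 3). The log2 fold change was 0.69 with SE 0.157 (edgeR, adjusted p = 0.00929), and every library labelled knockout lay above every library labelled wild type. With IgG the level was 143, 125, 154, 155 and 181 CPM (152 ± 20.2, SD, n = 5), and with PD1 it was 154, 177, 141, 158 and 157 CPM (157 ± 12.9, SD, n = 5), a log2 fold change of 0.05 with SE 0.104 (edgeR, adjusted p = 0.931). Transcripts of a gene disrupted by a small deletion are still counted, so the count of reads per gene does not show whether protein was made, and the tables hold no reads to show an edit. The treated table places Arid1a on chromosome 4, from 133679008 to 133756769 on GRCm38, where the microRNA gene Mir7227 overlaps it. The untreated table places it on chromosome 4 from 133406319 to 133484080, on a build that was not settled.

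**Figure D1:**
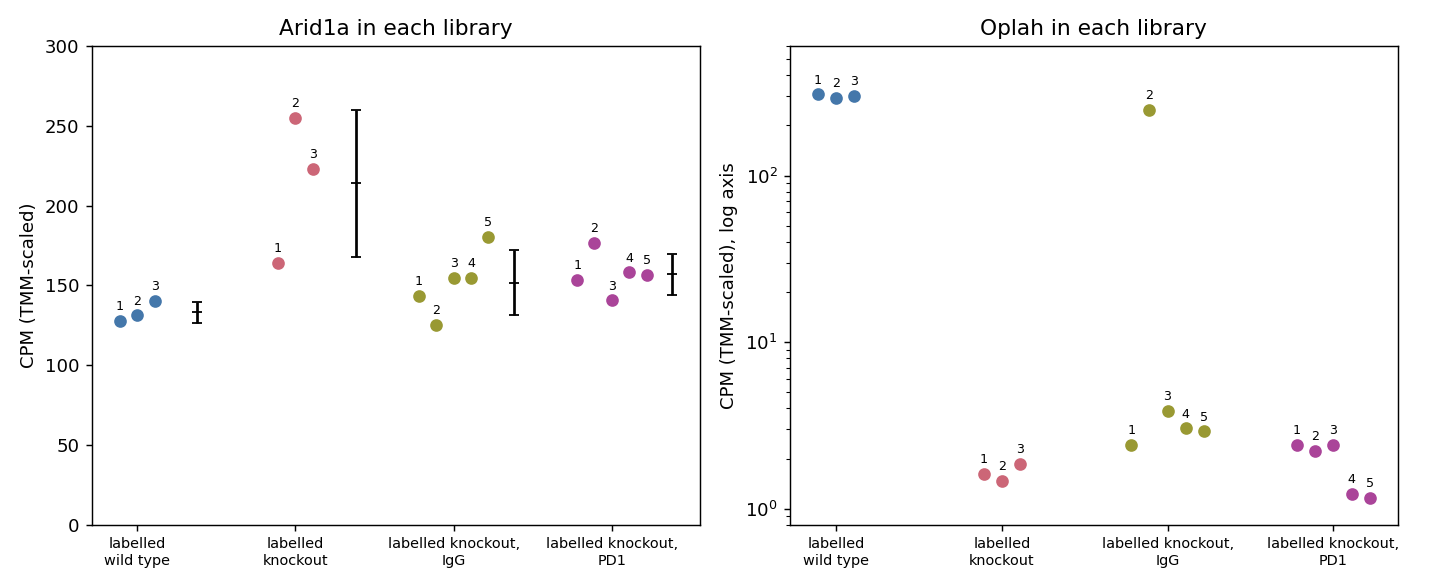
Points give the CPM of Arid1a (left, linear axis, with mean and SD) and of Oplah (right, log axis) in each of the 16 libraries, by group. Arid1a was 128 to 140 CPM in the libraries labelled wild type and 164 to 255 CPM in the untreated libraries labelled knockout, and Oplah was 247 CPM in IgG replicate 2 and 1.16 to 3.85 CPM in the other 9 treated libraries.

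The series asks which genes differ between ARID1A wild-type and mutant cells, and the untreated libraries were compared by their labels. An effect of the genotype cannot be told apart here from one of the clone that was grown. Interferon-stimulated genes rose together in the libraries labelled knockout, where 45 of 48 measured members were called higher and Ifit1, which blocks translation of viral RNA, went from 7.15 ± 0.501 to 174 ± 24.1 CPM (SD, n = 3), 24.3-fold. Cholesterol synthesis genes (16 of 22) and glycolysis and hypoxia genes (23 of 26) fell, though Ndrg1 of the second list rose. The list calls ended at adjusted p = 0.278 for interferon, 0.109 for cholesterol and 0.884 for glycolysis with an estimated correlation. Hmgcs1, which makes the precursor of mevalonate, was at 77.8 ± 2.68 CPM in the libraries labelled wild type and 19.1 ± 1.79 CPM in those labelled knockout. Ptgs2, the inducible cyclooxygenase that starts prostaglandin synthesis from arachidonic acid, rose from 179 ± 3.15 to 509 ± 107 CPM, 2.83-fold. Oplah, the 5-oxoprolinase of the glutathione cycle, was nearly lost, at 299.7 ± 7.43 CPM in the libraries labelled wild type and 1.65 ± 0.193 CPM in those labelled knockout. Genes of chromosome 17 lay lower as a block, at a median log2 fold change of -0.47.

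Of 13832 genes tested, edgeR called 6640 (48.0%), of which 3418 were higher and 3222 lower in the libraries labelled knockout. At least 2-fold changes were seen in 2444 of them, 1424 higher and 1020 lower. The groups did not overlap in 60.2% of the genes tested, where chance gives 10%. The first principal component held 78.0% of the variance and parted the groups. The second held 12.5% and parted replicate 1 (38.0) from replicate 2 (-31.5) of the libraries labelled knockout. Of the 30 lists with enough measured members, camera called 8, 2 higher and 6 lower. With an estimated correlation it called 0 of them (smallest adjusted p = 0.109, with 3 lists at an unadjusted p below 0.05), and fry called 14. Fry alone called arachidonic acid metabolism, cytokines and chemokines, immune checkpoints, and markers of T cells, B cells, dendritic cells and fibroblasts, each higher. TNF/NF-kB targets and immediate early and heat shock genes were called by fry alone, each lower. Fry's adjusted p ran from 0.00426 to 0.0312 over these lists.

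The interferon list held the strongest shift: 45 of 48 measured members rose and 2 fell, and the counts adjusted over the list alone were 45 and 2. The median log2 fold change was 2.57 (camera, adjusted p = 2.88e-20; adjusted p = 0.278 with an estimated correlation). Besides Ifit1 (log2 fold change 4.60, SE 0.143, edgeR adjusted p = 6.00e-06), Xaf1, an inducer of apoptosis, rose by 2.86 and Ifi44 by 3.29 on the log2 scale. Stat1, the transcription factor that carries interferon signals, rose by 1.96, Cxcl10, a chemokine that attracts T cells, by 3.66, and Cd274, which encodes the PD1 ligand, by 2.27. The members that fell were Irf8, a transcription factor of the myeloid lineage, from 2.61 to 0.0218 CPM (0 counts without knockout replicate 2), and Socs1, a suppressor of cytokine signalling (log2 fold change -0.65). The Socs1 call ended without any replicate labelled wild type and without knockout replicate 1 or 3 (adjusted p 0.0514 to 0.112). Bst2 was not called, at 0.58, but was called at 0.85 without knockout replicate 2 (adjusted p = 0.00324). Of the 22 listed genes of MHC class I antigen presentation, 20 were measured, 5 rose and 4 fell (6 and 4 adjusted over the list alone; camera, adjusted p = 0.909). Nlrc5, the transactivator of MHC class I genes, rose by 1.30 and Tapbpl, a peptide editor, by 0.81, with B2m, the light chain of MHC class I, at 0.93 and the peptide transporter subunit Tap1 at 0.99. Psmb8, an immunoproteasome subunit, fell by 4.67 on the log2 scale, to 0.392 ± 0.229 CPM, and the transporter subunit Tap2 fell by 0.66, a call that ended without any replicate labelled wild type and without knockout replicate 3 (adjusted p 0.0973 to 0.143). Psmb8 and Tap2 lie on chromosome 17, but so does Tap1, which lay higher.

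Arachidonic acid genes moved in both directions. Of 29 measured members, 8 rose and 5 fell, as they did adjusted over the list alone, with a median log2 fold change of -0.07 and a mean of 0.14 (camera, adjusted p = 0.831). Fry, which sets a list against no other genes, called it higher (adjusted p = 0.0312). Pla2g2e, a secreted phospholipase that frees fatty acids from membrane lipids, rose from 14.2 ± 1.17 to 46.9 ± 5.83 CPM (log2 fold change 1.73, SE 0.127, edgeR adjusted p = 7.16e-05). The epidermal lipoxygenase Aloxe3 rose by 3.06, to 6.58 ± 0.893 CPM. Ptgs2 rose 2.83-fold, with an SE of 0.158 on the log2 scale (edgeR, adjusted p = 0.000306). Ptges, the inducible synthase that makes prostaglandin E from the product of cyclooxygenase, fell from 187 ± 5.74 to 87.9 ± 16.3 CPM, and Ptgs1, the constitutive cyclooxygenase, fell from 218 ± 14.0 to 159 ± 10.9 CPM. Pla2g4a, the main cytosolic phospholipase of arachidonic acid release, was 128 ± 3.88 CPM in the libraries labelled wild type and 136 ± 12.9 CPM in those labelled knockout and was not called. Of 6 measured prostaglandin and leukotriene receptor genes, 2 rose and 0 fell by edgeR (1 and 0 adjusted over the list alone; camera, adjusted p = 0.565). Ptger2, a receptor of prostaglandin E, rose by 1.76 from 0.422 ± 0.0993 CPM (edgeR, adjusted p = 0.0137), a call that ended without wild-type replicate 2 (adjusted p = 0.0551) and without knockout replicate 3 (adjusted p = 0.0561). The other was Ptger1, at 0.78, whose call ended without any replicate labelled wild type and without knockout replicate 1 or 3 (adjusted p 0.0662 to 0.133).

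**Figure D2:**
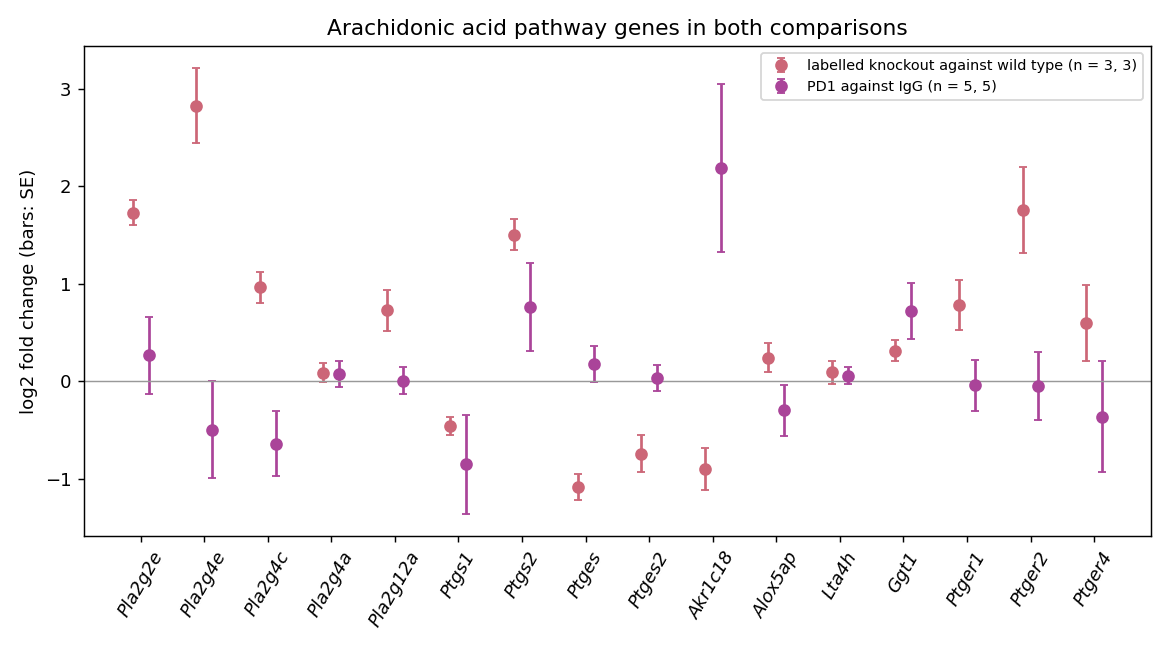
Points give the log2 fold change of 16 genes of arachidonic acid metabolism and its receptors in both comparisons, with the SE as bars. Pla2g2e was at 1.73 and Ptges at -1.09 between the untreated groups, and between PD1 and IgG no gene of the list was called.

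The lists of cholesterol synthesis, glycolysis and hypoxia, and fatty acid synthesis had medians below 0 in the libraries labelled knockout. In the cholesterol list, 0 of 22 measured members rose and 16 fell (0 and 17 adjusted over the list alone), at a median of -1.01 (camera, adjusted p = 3.31e-07; adjusted p = 0.109 with an estimated correlation). Hmgcs1 fell by 2.03 on the log2 scale (SE 0.104, edgeR adjusted p = 2.25e-05), Hmgcr, the rate-limiting enzyme of the pathway, fell by 0.87 and Ldlr, the receptor for low-density lipoprotein, fell by 1.10. In the glycolysis and hypoxia list, 1 of 26 rose and 23 fell, and the same counts were found adjusted over the list alone, at a median of -0.83 (camera, adjusted p = 1.66e-06; adjusted p = 0.884 with an estimated correlation). The phosphofructokinase gene Pfkl fell by 1.85, enolase Eno1 fell by 1.54 and the hypoxia-induced carbonic anhydrase Car9 fell by 2.10, whereas Ndrg1, a stress-induced gene, rose from 514 ± 62.3 to 1457 ± 111 CPM. In the fatty acid list, 4 of 20 rose and 13 fell (5 and 13 adjusted over the list alone), at a median of -0.46 (camera, adjusted p = 0.0397; adjusted p = 0.494 with an estimated correlation). Acly, which makes the acetyl-CoA for lipid synthesis, fell by 0.90, the fatty acid synthase Fasn fell by 0.96, and Acsl1, which activates fatty acids, rose by 1.02. The call of this list ended without wild-type replicate 3 (adjusted p = 0.0503), without knockout replicate 1 (adjusted p = 0.0863), with a replicate block (adjusted p = 0.0554) and with GC and length trends removed (adjusted p = 0.0840). Of 21 glutathione and NRF2 targets, 5 rose and 7 fell (6 and 7 adjusted over the list alone; camera, adjusted p = 0.824), with the quinone reductase Nqo1 up by 1.98.

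In the list of cell cycle G2/M genes, 0 of 25 rose and 14 fell, as they did adjusted over the list alone, at a median of -0.38 (camera, adjusted p = 0.00176; adjusted p = 0.884 with an estimated correlation). Cenpf, a kinetochore protein, fell from 204 ± 22.6 to 80.9 ± 11.6 CPM. Of 27 DNA replication genes, 8 rose and 4 fell (6 and 4 adjusted over the list alone; camera, adjusted p = 0.804), and the polymerase subunit Pola1 fell by 0.60. Of 26 mismatch repair and DNA damage genes, 7 rose and 8 fell, the same counts as adjusted over the list alone (camera, adjusted p = 0.804). Mdm2, the p53-induced ligase that degrades p53, rose from 179 ± 3.39 to 495 ± 54.6 CPM. In the list of unfolded protein and amino acid stress, 5 of 19 rose and 4 fell, likewise adjusted over the list alone (camera, adjusted p = 0.824), and Ddit3, a stress-induced transcription factor, rose by 1.71. Of 15 immediate early and heat shock genes, 3 rose and 6 fell (4 and 7 adjusted over the list alone; camera, adjusted p = 0.528), with the chaperone gene Hsph1 lower by a log2 fold change of -1.33. Of 20 TNF/NF-kB targets, 6 rose and 10 fell (6 and 11 adjusted over the list alone; camera, adjusted p = 0.528), among them Nfkbie, an inhibitor of NF-kB, at -1.72.

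Of 26 measured SWI/SNF subunits, 8 rose and 3 fell, the same as adjusted over the list alone (camera, adjusted p = 0.565). Bcl7b rose by 0.89 (SE 0.0930, edgeR adjusted p = 0.000292), Smarcd1 by 0.74, Dpf2 by 0.66 and the ATPase subunit Smarca2 from 17.1 ± 1.30 to 36.2 ± 9.91 CPM. The neuronal subunit Dpf1 fell by 0.90. Arid1b, the paralog of Arid1a, was at -0.33 and was not called, but was called at -0.47 without knockout replicate 2 (adjusted p = 0.0124). Of 19 measured cytokine and chemokine genes, 10 rose and 5 fell, also when adjusted over the list alone, at a median of 0.52 (camera, adjusted p = 0.565). Il34, a ligand of the CSF1 receptor, fell by 1.74 and Tgfb3 fell by 1.36. Ccl7, a monocyte chemokine, had 0 counts in the libraries labelled wild type and 0.740 ± 0.154 CPM in those labelled knockout, at least 27.5-fold higher. In the angiogenesis list, 8 of 22 rose and 9 fell (9 and 9 adjusted over the list alone; camera, adjusted p = 0.824). The EGF receptor ligand Areg rose by 1.61, the VEGF co-receptor Nrp1 fell by 1.37, and the growth factor Pdgfc fell by 4.26, or by 5.03 without knockout replicate 2. Of 20 genes of the epithelial-mesenchymal transition, 6 rose and 8 fell (7 and 8 adjusted over the list alone; camera, adjusted p = 0.688). The intermediate filament gene Vim fell from 3860 ± 36.4 to 1791 ± 218 CPM, Twist2, a mesenchymal transcription factor, rose by 1.45, and the keratin gene Krt19 fell by 3.90, or by 5.11 without knockout replicate 3, from 0.699 ± 0.0138 CPM.

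**Figure D3:**
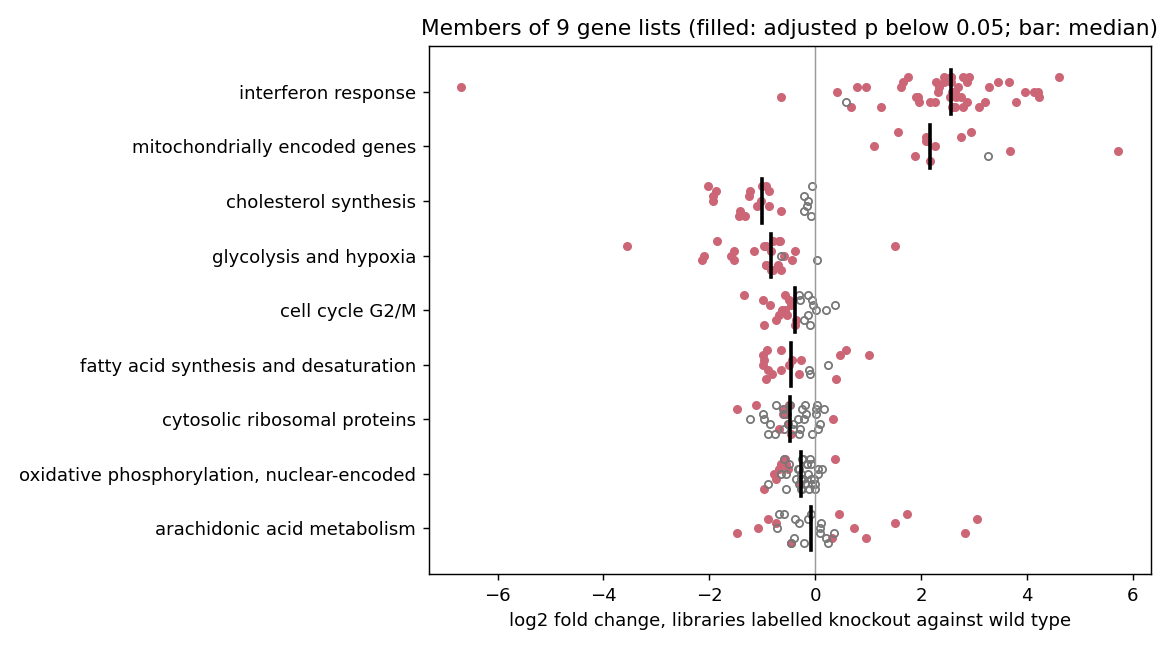
Points give the log2 fold change of each measured member of 9 gene lists, libraries labelled knockout against wild type, with filled points for an edgeR adjusted p below 0.05 and a bar at the median. The interferon median lay at 2.57, the cholesterol median at -1.01 and the arachidonic acid median at -0.07.

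All 13 mitochondrially encoded genes were measured, 12 rose and 0 fell by edgeR (13 and 0 adjusted over the list alone), at a median of 2.17 (camera, adjusted p = 0.00515; adjusted p = 0.884 with an estimated correlation). Their median shift from the libraries labelled wild type was 0.83, 3.05 and 1.67 in knockout replicates 1, 2 and 3, and without replicate 2 the median was 1.29 with 10 genes higher. mt-Nd3, a subunit of complex I, rose by 1.57. mt-Atp8, a subunit of ATP synthase, rose from 2.42 ± 0.231 to 128 ± 171 CPM, with 4.54, 323 and 55.5 CPM in replicates 1, 2 and 3. Its log2 fold change of 5.72 became 3.63 without replicate 2 and 4.39 with a replicate block. Among 42 nuclear genes of oxidative phosphorylation, 1 rose and 9 fell (0 and 4 adjusted over the list alone), at a median of -0.26 (camera, adjusted p = 0.0190; adjusted p = 0.885 with an estimated correlation). Among 38 cytosolic ribosomal protein genes 1 rose and 9 fell (0 and 2 adjusted over the list alone), at a median of -0.48 (camera, adjusted p = 0.0110; adjusted p = 0.885 with an estimated correlation). Ndufb10, a complex I subunit, fell by 0.57 and Rps2 fell by 0.49. Both lists moved with the mitochondrial share: the median shift of the oxidative phosphorylation genes was 0.08, -0.64 and -0.44 in replicates 1, 2 and 3, and that of the ribosomal genes was 0.03, -0.88 and -0.62. Without knockout replicate 2 both calls ended, at adjusted p = 0.262 and 0.164, and that of oxidative phosphorylation ended without replicate 3 (adjusted p = 0.0579). By fry none of these 3 lists was called, at adjusted p = 0.0633 for the mitochondrially encoded, 0.254 for the oxidative phosphorylation and 0.236 for the ribosomal genes.

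On chromosome 17, 458 genes with a log2 CPM above 3 had a median log2 fold change of -0.47, and 258 of them were called lower against 39 higher. Their log2 fold change was below 0 in 80.1% of the genes, where it was in 52.1% on the other autosomes, whose medians lay between -0.15 and 0.10. The median of chromosome 17 was -0.40, -0.52 and -0.52 in knockout replicates 1, 2 and 3. Psmb8, Tap2, Notch4, Ndufb10, Nfkbie, Plin4 and Rps2, all named here as lower, lie on it, and so does Tap1, which lay higher. Ndufb10 (-0.57) and Rps2 (-0.49) lay near the median of the chromosome. Psmb8 (-4.67), Notch4 (-3.97), Nfkbie (-1.72) and Plin4 (-1.65) lay far below it, so the shift of the block does not account for the size of their falls.

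**Figure D4:**
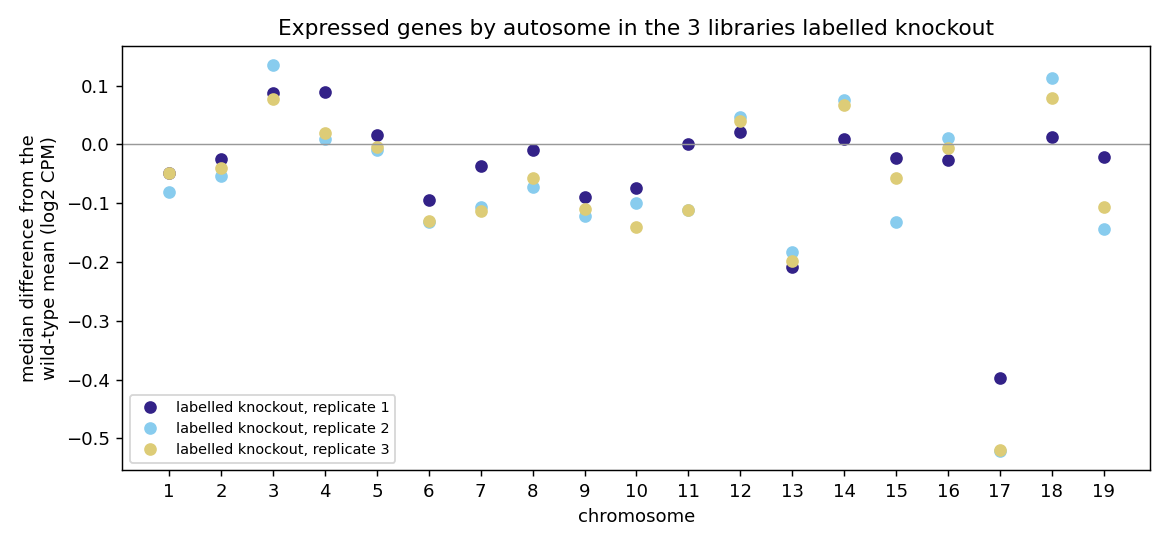
Points give, for each autosome and each of the 3 libraries labelled knockout, the median shift in log2 CPM of its genes from the mean of the libraries labelled wild type. Chromosome 17 lay at -0.40, -0.52 and -0.52.

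The largest changes of single genes, taken by the fixed rule, lay in part outside the lists. Besides mt-Atp8 and Ifit1, the rises were Abca4, a retinoid transporter, to 11.5 ± 1.72 CPM (log2 fold change 5.17, or 5.91 without wild-type replicate 1), Omd, a matrix proteoglycan, to 56.9 ± 33.8 CPM (5.02, or 4.43 without knockout replicate 2) and the protease inhibitor Serpinb6b to 11.5 ± 0.644 CPM (4.53). The falls were Oplah (-7.50, SE 0.127, edgeR adjusted p = 2.19e-07), Ttc9 (-7.46, from 12.1 ± 0.120 CPM), Psmb8, the kinase Syk of immune receptor signalling (-4.46) and the receptor Notch4 (-3.97). On log2(FPKM + 1) several were smaller and kept their calls: Oplah -5.36, Ttc9 -1.81, Psmb8 -1.83, Notch4 -1.62, mt-Atp8 4.06, Omd 3.72 and Serpinb6b 2.31, with Nfkbie at -1.12 and Lyz2 at 1.67. Another 24 tested genes had 0 counts in a whole group, among them Lrriq1, at least 203-fold lower, and Tnik, a kinase of Wnt signalling, at least 90.1-fold higher in the libraries labelled knockout. Some named genes overlap other genes, and without strand their counts could hold reads of the neighbour: Omd lies in Cenpp, Oplah beside Exosc4 and Smpd5, mt-Atp8 beside mt-Atp6, Ddit3 beside Mars1, Tapbpl beside Vamp1, Tgfb3 in Ttll5, Plin4 beside Hdgfl2, Rps2 beside Snhg9 and Nlrc5 with 9330175E14Rik. Predicted or noncoding gene models overlap Ptger2, Dpf2, Smarcd1, Il34, Twist2, Hmgcs1, Eomes and Sbsn.

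Markers of other cell types were counted in the untreated libraries. Of the listed markers, 3 of 26 for T cells, 0 of 11 for NK cells, 4 of 13 for B cells, 7 of 23 for macrophages, 2 of 14 for neutrophils and 4 of 18 for dendritic cells and MHC class II passed the count filter. So did 3 of 15 for endothelium, 12 of 18 for fibroblasts and matrix, 4 of 15 for keratinocytes, 4 of 15 for skeletal muscle, 2 of 11 for adipocytes and 2 of 8 for erythroid cells. Camera called no such list. Camera's adjusted p was 0.394 for T cells, 0.831 for B cells, 0.831 for macrophages and 0.824 for dendritic cells. It was 0.831 for endothelium, 0.141 for fibroblasts, 0.824 for keratinocytes and 0.688 for muscle. Fry called the lists of T cells (adjusted p = 0.00647), B cells (0.00426), dendritic cells (0.00490) and fibroblasts (0.00426), each higher. Their median log2 fold changes were 0.79, 0.00371, 0.30 and 0.76. The leukocyte marker Ptprc was at only 0.154 and 0.0233 CPM in the groups labelled wild type and knockout. The neutrophil, adipocyte and erythroid lists had too few measured members to be tested. For fibroblasts and matrix, 8 rose and 2 fell (8 and 3 adjusted over the list alone), with the collagen gene Col3a1 going from 33.8 ± 1.74 to 111 ± 9.61 CPM and Col1a1 from 197 ± 3.32 to 83.3 ± 22.8 CPM. For macrophages, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Lyz2, a lysozyme, up by 2.37. For dendritic cells, 2 rose and 1 fell, and the same was found adjusted over the list alone, with Cd74, the invariant chain of MHC class II, going from 9.84 ± 0.759 to 56.3 ± 5.44 CPM. T cell markers gave 2 rises and 0 falls by edgeR, also adjusted over the list alone, and B cell markers 1 and 0 in both counts. The B cell gene was Pax5, with 0 counts in the libraries labelled wild type and at least 27.9-fold higher in those labelled knockout. The T cell transcription factor Eomes rose by 1.05 to 0.527 ± 0.141 CPM (edgeR, adjusted p = 0.0353), a call that ended without any replicate labelled wild type, without knockout replicate 1 or 2, with a replicate block and in DESeq2 (adjusted p 0.0635 to 0.116). Both neutrophil genes rose in either count, and the receptor gene Csf3r was at 0.0185 and 0.515 CPM in the groups labelled wild type and knockout (log2 fold change 4.58), with 0 counts in its control group without wild-type replicate 1. Keratinocyte markers gave 2 rises and 1 fall in either count, the fall in Sbsn (-1.05). Muscle markers gave 1 rise and 0 falls in either count, in Actn3 (1.14), whose call ended without any replicate labelled wild type, without knockout replicate 2 or 3, with a replicate block and in DESeq2 (adjusted p 0.0535 to 0.103). Adipocyte markers gave 0 rises and 1 fall (1 and 1 adjusted over the list alone), in the lipid droplet gene Plin4 (-1.65). Erythroid markers gave 1 and 0 in either count, in Gypa at 0.0367 and 0.630 CPM (log2 fold change 3.25 without knockout replicate 2 and 3.41 without wild-type replicate 3), with 0 counts in its control group without wild-type replicate 2. Endothelial markers gave 0 and 0 in either count by edgeR. Among 12 immune checkpoint genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera, adjusted p = 0.565), with the galectin gene Lgals9 going from 77.0 ± 0.689 to 260 ± 21.9 CPM.

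Stat1, Cxcl10, Cd274, Irf8, Socs1, Bst2, B2m, Tap1, Tap2, Ptges, Ptgs1, Pla2g4a, Ptger1, Hmgcr, Ldlr, Eno1, Car9, Ndrg1, Fasn, Acsl1, Smarca2, Dpf1, Arid1b, Col1a1, Lrriq1 and Tnik were named outside the rule and chosen after their values were seen.

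The treated libraries set PD1 therapy against IgG in material labelled ARID1A knockout. They held leukocyte and endothelial transcripts that the untreated libraries nearly lacked, so their values are not those of CT26 cells alone. The leukocyte marker Ptprc was 105 ± 30.4 CPM with IgG and 83.0 ± 47.1 CPM with PD1 (SD, n = 5 each). Over all genes tested, edgeR called no gene between PD1 and IgG, while DESeq2 called 1. The values below therefore describe the libraries and the lists, without a change shown by edgeR for any gene over all genes tested. Skeletal muscle markers, by a median log2 fold change of -2.17, and marker genes of macrophages (-0.39), dendritic cells and MHC class II (-0.47) and NK cells (-0.34) lay lower with PD1, and markers of neutrophils (0.92) and genes of glycolysis and hypoxia (0.28) lay higher. Each of these list calls ended when a single library was left out. None stood with an estimated correlation (adjusted p = 0.789 for each), and fry called 0 lists. Ptgs2 was 205 ± 114 CPM with IgG and 348 ± 164 CPM with PD1 (SD, n = 5 each), a log2 fold change of 0.76 with SE 0.456 (edgeR, adjusted p = 0.879).

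Of 15899 genes tested, edgeR called 0 (smallest adjusted p = 0.879), and 620 had an unadjusted p below 0.05 where 795 are expected by chance. DESeq2 called 1, the pseudogene Gm10736 (log2 fold change -1.39, adjusted p = 0.0187; -1.40 and adjusted p = 0.879 in edgeR), with 878 genes at an unadjusted p below 0.05, and limma-voom with quality weights called 0 with 2246. Without PD1 replicate 2, edgeR called 0, with 2838 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.161. All 34 lists were tested. Camera called 12, 4 higher and 8 lower with PD1, whereas 0 were called with an estimated correlation (smallest adjusted p = 0.789) and 0 by fry, with 0 lists at an unadjusted p below 0.05 in either. By edgeR 0 members of any list were called, and adjusted over the list alone only 2 muscle genes were called, Acta1 (-4.87) and Tnnt3 (-3.31), both lower. Scaled to the total count, Acta1 was 168 CPM in IgG replicate 5 and 0.793 to 7.12 CPM in the other IgG libraries. With PD1 it was 0.217 to 1.64 CPM, so its fold change rests largely on IgG replicate 5.

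Markers of immune cells and muscle each had adjusted p = 0.789 with an estimated correlation. Camera's adjusted p was 0.0200 for muscle, macrophages, dendritic cells and neutrophils, 0.0330 for NK cells and 0.0495 for T cells (median -0.20). The mean log2 CPM of the macrophage list was 3.50 in PD1 replicate 5 and 5.49 to 6.78 in the other treated libraries, and that of the T cell list was 0.32 and 1.58 to 3.18. Differences with a library left out are means of the members' log2 CPM differences, so they do not compare directly with the medians above. Without PD1 replicate 5, the T cell mean difference was 0.05 and not called, and that of macrophages was -0.02 (camera, adjusted p = 0.949). Camera's adjusted p was then 0.569 for both NK cells and dendritic cells. The muscle list had a mean log2 CPM of 5.18 in IgG replicate 5 and 0.805 to 1.96 in the other IgG libraries. Without IgG replicate 5, the muscle mean difference was -0.41 (camera, adjusted p = 0.116). Camera's adjusted p was then 0.109 for T cells, 0.0656 for NK cells, macrophages and neutrophils and 0.0516 for dendritic cells. Other replicates ended calls as well: the neutrophil call ended without IgG replicate 1 (adjusted p = 0.142) or PD1 replicate 1 (0.108), 2 (0.0669) or 4 (0.0768). The T cell call ended without IgG replicate 3 (0.0766) or 4 (0.130) or PD1 replicate 4 (0.275) and with a replicate block (0.0525). The NK cell call ended without IgG replicate 4 (0.0706) or PD1 replicate 4 (0.0536). The dendritic cell call ended without IgG replicate 2 (0.0625), and the muscle call without PD1 replicate 2 (0.0558).

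Among the metabolic and signalling lists, nuclear genes of oxidative phosphorylation lay lower with PD1 at a median of -0.11 (camera, adjusted p = 0.000811; adjusted p = 0.789 with an estimated correlation), and this was the only list whose camera call stood with each of the 10 libraries left out in turn. With GC and length trends removed its mean difference was 0.03 (adjusted p = 0.618). Glycolysis and hypoxia genes lay higher (0.28, adjusted p = 0.00150), a call that ended without IgG replicate 5 (adjusted p = 0.0656). Glutathione and NRF2 targets lay higher (0.11, adjusted p = 0.0200), a call that ended without IgG replicate 3 (0.0537) or PD1 replicate 2 (0.0742). Mitochondrially encoded genes lay lower (-0.41, adjusted p = 0.0253), and the call ended without IgG replicate 2 (0.0530), 3 (0.0778) or 5 (0.109) or PD1 replicate 5 (0.163). Cholesterol genes lay lower (-0.13, adjusted p = 0.0436), and the call ended without IgG replicate 1 (0.435) or 3 (0.0731), without PD1 replicate 1 (0.0577), 2 (0.375) or 4 (0.268) and with GC and length trends removed (0.0526). Interferon genes lay higher by a median log2 fold change of 0.06 (adjusted p = 0.0375). Without IgG replicate 2 they lay lower, at a mean difference in log2 CPM of -0.13 (adjusted p = 0.0256). They lost the call without PD1 replicate 1 (0.203), 2 (0.751) or 3 (0.178), with GC and length trends removed (0.0743) and with the mitochondrially encoded genes left out (0.0505). Each of these lists had adjusted p = 0.789 with an estimated correlation.

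Arachidonic acid genes were not called as a list (34 measured, median -0.08; camera, adjusted p = 0.416), nor were their receptors (10 measured; adjusted p = 0.129). By the fixed rule the named genes here are list members with the smallest p, and none passed the test. Akr1c18, an aldo-keto reductase that acts on prostaglandins and progesterone, was 9.80 ± 10.9 CPM with IgG and 44.9 ± 34.9 CPM with PD1 (log2 fold change 2.19, SE 0.860), or 3.14 without IgG replicate 4. Cd274 was 64.2 ± 19.7 and 93.5 ± 28.0 CPM (0.54, SE 0.274). The MHC class I gene H2-Q7 was at 1.29, or 0.59 without PD1 replicate 1, the interleukin gene Il1a, which Gm14023 overlaps, at 1.07, the T cell adhesion gene Cd2 at 0.54 and the nitric oxide synthase gene Nos2 at 0.87, all with edgeR adjusted p = 0.879. Of arachidonic acid genes chosen after their values were seen, Ptgs1 was 56.8 ± 56.9 CPM with IgG and 31.4 ± 6.44 CPM with PD1, a log2 fold change of -0.85 that became 0.00 without IgG replicate 2 (157 CPM). Ptges was at 0.18 and Pla2g2e at 0.26, or -0.18 without PD1 replicate 4, and none was called.

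The other lists were not called between PD1 and IgG. Camera's adjusted p was 0.854 for SWI/SNF subunits, 0.183 for MHC class I, 0.419 for cytokines and chemokines, 0.0583 for angiogenesis factors and 0.0583 for the epithelial-mesenchymal transition. It was 0.164 for cell cycle G2/M, 0.670 for DNA replication, 0.908 for fatty acid synthesis, 0.164 for TNF/NF-kB targets, 0.183 for mismatch repair and DNA damage and 0.164 for the unfolded protein response. It was 0.129 for B cells, 0.313 for immune checkpoints, 0.257 for endothelium, 0.183 for fibroblasts and matrix, 0.680 for keratinocytes, 0.112 for adipocytes, 0.0884 for erythroid genes, 0.112 for immediate early and heat shock genes and 0.129 for ribosomal proteins. The median, the mean and the camera direction of a list differed in sign for 5 lists between the untreated groups (arachidonic acid metabolism, MHC class I, glutathione and NRF2 targets, mismatch repair, macrophages) and for 2 between the treated groups (SWI/SNF subunits, DNA replication). Camera called 0 of these lists, and fry called only arachidonic acid metabolism, between the untreated groups.

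**Figure D5:**
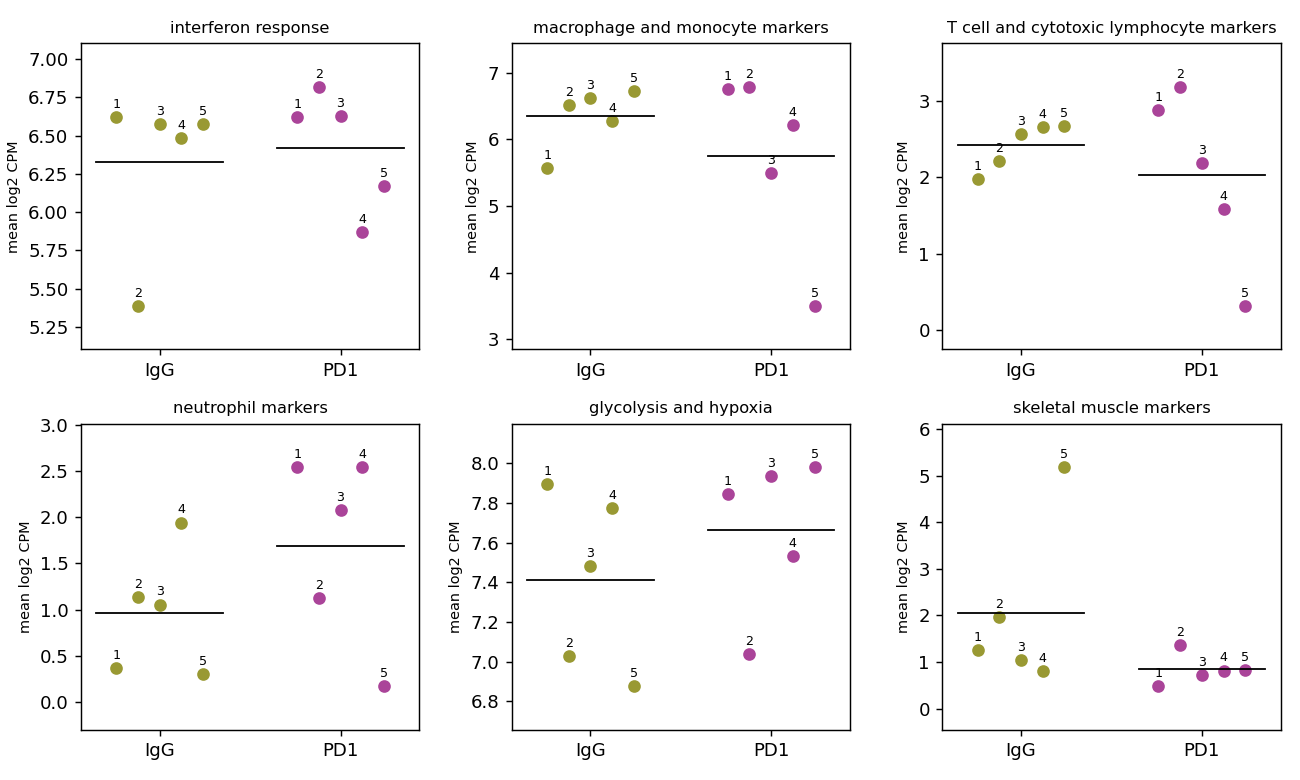
Points give the mean log2 CPM of the members of 6 gene lists in each of the 5 IgG and 5 PD1 libraries, with a line at the group mean. The macrophage value of PD1 replicate 5 was 3.50, below the 5.49 to 6.78 of the other treated libraries, and the interferon value of IgG replicate 2 was 5.39.

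Genes that differed between the untreated groups were also followed under therapy, in libraries that share none with the first comparison. Of the 1424 genes called at least 2-fold higher in the untreated libraries labelled knockout, 1048 were measured in the treated libraries, where they lay higher with PD1 by a median of 0.03 (camera, adjusted p = 0.0113; adjusted p = 0.302 with an estimated correlation; fry, p = 0.642). Of the 1020 called lower, 895 were measured and lay lower by a median of -0.12 (camera, adjusted p = 0.000822; adjusted p = 0.272 with an estimated correlation; fry, p = 0.0598). Without IgG replicate 2, in which Oplah was 247 CPM, the mean difference of the first set was -0.02 (adjusted p = 0.882) and that of the second -0.04 (adjusted p = 0.0941), and without PD1 replicate 2 that of the first was 0.02 (adjusted p = 0.365).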

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

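The tests of Arid1a, of chromosome copies in the libraries labelled knockout, and of the wild-type profile, leukocytes and RNA quality in IgG replicate 2 were chosen only after the result was seen, as was the choice of these 3 patterns, while the tests of GC bias, RNA quality and the MHC region on chromosome 17, of chromosome 17 in IgG replicate 2, and of other splits of the libraries were written before their results.

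Arid1a was higher in the untreated libraries labelled knockout, at 214 ± 46.1 against 133 ± 6.40 CPM (SD, n = 3). A scaling effect was argued against, since the log2 fold change was 0.68 at its lowest over RLE, upper-quartile scaling and leaving out the mitochondrially encoded genes. Knockout replicates 1, 2 and 3, at 164, 255 and 223 CPM, had the order of their mitochondrial shares (2.57%, 9.72% and 4.53%). Without replicate 2 the log2 fold change was 0.53 (edgeR, adjusted p = 0.0119). Whether library quality added to the difference was not tested. A swap of a single library was argued against, since the lowest correlation across genes within a group exceeded the highest between groups by 0.0189. A swap of the whole untreated groups was argued against only if the treated libraries, all labelled knockout, were labelled rightly. Oplah had a median of 0.805% of the wild-type level over those 10 libraries. A first form of this test asked for under 10% in each library. It was restated as a median after IgG replicate 2, at 82.3%, broke it. A swap of the cells before both sets of libraries were made would give the same values and stays open. What also stays open is whether an edit that leaves the transcript may have been made, which counts per gene do not show.

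Genes of chromosome 17 lay lower in the libraries labelled knockout, with a shift of -0.44 on the log2 scale against the other autosomes. GC content and length bias was argued against, as the shift was -0.40 after these trends were removed. Low RNA quality of knockout replicate 2 was argued against by a shift of -0.37 in the weaker of replicates 1 and 3, and the MHC region alone by a shift of -0.44 without the genes at 30 to 40 Mb. Of the bins of 10 Mb with at least 20 genes, 8 of 8 had a median below -0.2, from -0.56 to -0.22, which is consistent with fewer copies of the whole chromosome in the cells of these libraries. This is a hypothesis found and tested on the same data. Whether it goes with the genotype or with the clone that was grown cannot be told from these libraries. The same holds for the other differences between the untreated groups.

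IgG replicate 2 stood apart from the other 9 treated libraries, with Oplah at 247 CPM (82.3% of the mean of the libraries labelled wild type, across separately made tables, against 0.387 to 1.29%), Ttc9 at 9.67 CPM (0.757 to 3.42 in the others) and the lowest Arid1a level, 125 CPM (141 to 181). Fewer leukocytes were argued against, as Ptprc, a marker of all leukocytes, was 92.6 CPM and above 4 of the other 9 libraries. The bound of this test was reworded after its value was seen. The mitochondrial share of this library, 2.33%, lay within the range of 1.10 to 3.24%. That share does not measure RNA integrity, so low RNA quality was left open. Cells with the full number of chromosome 17 copies fit, as its chromosome 17 genes lay 0.34 higher than in the other 9 libraries (-0.14 to 0.14 for the others). Cells with the wild-type profile stay open: the genes lower in the untreated libraries labelled knockout had a median of 0.246 in this library (-0.11 to 0.04 in the others), short of the 0.3 the test asked for, and their fold changes together with those of the higher genes correlated with the knockout fold change across 1943 genes at -0.42 (-0.03 to 0.13), where genes are not independent replicates. A wrong label and a mixed library could each give these values.

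Values far from the rest of their group by Dixon's test were found for 12 of 90 values tested, where chance gives about 1 in 20. With IgG, the second principal component was -59.5 in replicate 2 (-1.43 or above in the others). The interferon list had a mean log2 CPM of 5.39 in replicate 2 (6.49 to 6.62). Akr1c18 was 28.6 CPM in replicate 4 (0.624 to 8.32). Il1a was 0.916 CPM in replicate 3 (0.416 to 0.535). Cytokines and chemokines had a mean log2 CPM of 2.05 in replicate 1 (2.77 to 2.84). Fatty acid genes were at 6.77 in replicate 1 (6.46 to 6.53). Unfolded protein response genes were at 6.25 in replicate 3 (6.70 to 6.79). Muscle markers were at 5.18 in replicate 5 (0.805 to 1.96). Mitochondrially encoded genes were at 6.23 in replicate 1 (7.55 to 8.07). With PD1, the mitochondrial share was 3.24% in replicate 2 (1.10 to 1.66%). Cytokines and chemokines had a mean log2 CPM of 1.35 in replicate 5 (2.83 to 3.28). TNF/NF-kB targets were at 4.44 in replicate 5 (5.24 to 5.54).

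Other splits of the same libraries were counted. Between the untreated groups, 1 of the 10 splits called as many genes as the 6640 found, which was the real split, and the highest other count was 0. For the lists it was likewise 1 of 10, with 8 lists against at most 7, and 10 splits are too few for a share under 0.05. Between PD1 and IgG, 100 of 100 splits drawn gave at least the 0 genes found, which any split does, so this count tests nothing. Only 3 of the 99 other splits called any gene, with 74 at most. Chance cannot be excluded for the lists, where 52 of 100 splits gave at least the 12 called and the highest other gave 23, nor for the 2 sets of genes that differed between the untreated groups, where 29 of 100 gave as many and the highest other gave 2.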

How the results depend on the processing

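Leaving out the mitochondrially encoded genes, removing GC and length trends, and leaving out IgG replicates 2 and 5 and PD1 replicate 5 together were chosen after the data were seen, and the other settings before. Where no cause is named, the cause was not tested. Between the untreated groups, 4643 to 8888 genes were called in 17 of 18 settings, and 10184 with limma-voom and quality weights. RLE factors shared 6629 of the 6640 called genes, and 38 called genes had the opposite sign after GC and length trends were removed. The log2 fold change of Arid1a was called in all 12 settings, at 0.53 to 0.99 (adjusted p 4.55e-05 to 0.0469). With upper-quartile factors 54.9% of the called genes were higher, and with FPKM 44.1 to 48.4%. Of the lists, 0 were called with an estimated correlation, 14 with fry and 6 to 8 with a library left out. Between PD1 and IgG, DESeq2 called 1 gene and the other settings 0. Of the lists, 0 were called with an estimated correlation, 0 with fry, 4 to 14 with a library left out (4 without IgG replicate 5) and 9 without the 3 libraries. Mean log2 CPM differences that turned without these 3 libraries were interferon -0.071, glycolysis and hypoxia -0.12, T cells 0.064, macrophages 0.16, dendritic cells and MHC class II 0.18 and mitochondrially encoded genes 0.071. That of oxidative phosphorylation turned to 0.026 with GC and length trends removed. With a library left out, interferon ran from -0.13 (without IgG replicate 2) to 0.24 and T cells from -0.66 to 0.052 (without PD1 replicate 5). Of the genes that differed between the untreated groups, the higher set was at 0.041 and the lower at -0.11 under PD1. With an estimated correlation neither was called at these values. Sets at any fold change gave -0.050 for the lower set, not called. A library left out gave -0.018 to 0.085 and -0.13 to -0.042, with both calls lost without IgG replicate 2. Among the values of named genes and lists, 796 kept direction and side of the threshold, 101 kept direction and lost the call, and 9 turned, the lists named here. The replicate numbers did not pair the libraries: same-numbered libraries correlated across genes at 0.0760, -0.0585 and 0.0775 after centring in the untreated groups and at -0.381 to 0.107 in the treated groups, and with the number as a block 6244 genes (5992 shared) and 0 genes were called. No paired analysis was therefore reported. No pair of libraries was a duplicate, with a chi-square per gene of at least 3.91. Depth limits genes near 0: the floor of 3 counts over a group was 0.0269 CPM in the libraries labelled wild type and 0.0326 CPM in those labelled knockout.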

Other observations

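The tests in this part were chosen only after the data were seen. The treated libraries held leukocyte and endothelial transcripts that the untreated libraries nearly lacked, with levels set here across separately made tables as CPM of the total count. The leukocyte marker Ptprc was 105 ± 30.4 CPM with IgG and 83.0 ± 47.1 CPM with PD1 (SD, n = 5 each), against 0.154 and 0.0233 CPM in the untreated libraries labelled wild type and knockout. C1qb, a complement gene of macrophages, was 244 ± 96.6 and 171 ± 127 CPM with IgG and PD1 and at most 0.0363 CPM as a group mean without treatment. Cd8a, a marker of cytotoxic T cells, was 21.6 ± 4.41 and 16.2 ± 13.6 CPM. The endothelial gene Pecam1 was 28.4 ± 8.21 and 29.2 ± 12.3 CPM, against at most 0.142 CPM without treatment. Col3a1 was present in both, at 472 ± 199 and 554 ± 158 CPM, against 33.9 and 111 CPM. The labels name CT26 cells for these libraries as well. The epithelial gene Epcam was 0.405 CPM in the libraries labelled wild type, 0 in those labelled knockout and 0.161 and 0.157 CPM with IgG and PD1. Krt18 was 22.7 and 22.2 CPM without treatment, and 25.4 ± 13.9 and 47.8 ± 16.8 CPM with IgG and PD1 (SD, n = 5 each).

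Among the 45 interferon genes called higher in the untreated libraries labelled knockout, 44 kept their call with GC and length trends removed and 45 without the mitochondrially encoded genes. KEGG pathways named in the annotation of the untreated table were tested with camera: of 306 pathways of 15 to 300 genes, 0 were called, with 44 at an unadjusted p below 0.05, and 0 were called with an estimated correlation, with 10 at an unadjusted p below 0.05. The smallest adjusted p was 0.0859, for chondroitin and dermatan sulfate synthesis, where 1 of 16 genes was called higher and 10 lower by edgeR. In the arachidonic acid pathway, 9 of 32 genes were called higher and 4 lower (adjusted p = 0.841).

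A hypothesis was that the main axis of the treated libraries follows the amount of macrophage RNA. The first principal component held 41.8% of the variance, and over the 10 libraries it correlated with the mean log2 CPM of the macrophage list at r = 0.969 (permutation p = 0.00018, adjusted 0.0009 over 5 relations) and rho = 0.830 (permutation p = 0.00437), at 0.896 without the 2 farthest libraries and at 0.967 within groups. The T cell list gave r = 0.870 (permutation p = 0.00453, adjusted 0.0113), rho = 0.721 (permutation p = 0.0236) and 0.639 without the 2 farthest. The fibroblast list gave r = 0.717 (permutation p = 0.0251, adjusted 0.0418), rho = 0.382 (permutation p = 0.280) and -0.334 without the 2 farthest, so that relation rests on those libraries. The neutrophil list gave r = 0.273 and rho = 0.103 (permutation p = 0.474 and 0.787), and the ribosomal list r = 0.210 and rho = 0.115 (permutation p = 0.536 and 0.760), both adjusted to 0.536 for r. The component was computed from genes that include these lists, so the relation is partly circular. The values are consistent with libraries that differ in how much macrophage RNA they hold, and PD1 replicate 5, with the lowest Ptprc level (13.1 CPM against 61.3 to 143 CPM), lay at the far end.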
